A study of Mus musculus with 6 samples.

How the data were processed

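RNA from tumour-associated macrophages of PyMT mice was profiled on 6 arrays of 1 colour, 3 with and 3 without chemotherapy. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, amplified and labelled with Cy3 from low input. Per the submitters' processing notes, Agilent Feature Extraction 10.7 was used. The background correction, the normalization and any filter were not given in the sources used here, and no scanner file, detection flag, slide or scan date was used here.

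The deposited table of the authors holds 1 value per probe and array, which was read as log2 intensity. This reading rests on the values: they run from 1.86 to 18.7, and the spike-in probes rise in steps as a dilution series does. The quartiles of the 6 arrays nearly coincide (medians 6.46 to 6.47), so the values had been brought to a common distribution before they were deposited; the method is not known. Such a step removes any overall difference in RNA output between arrays, and the values are not centred per probe. The lowest values lie at a floor near 2, where order carries little information. Of the 90808 probes, 56 controls were kept out of all tests: 10 E1A and 18 DCP probes, 12 ERCC probes, 13 ETG probes, and a negative control, a dark and a bright corner probe. The first DCP probe of the series numbered 20 and 22 lay within 0.065 of the E1A probe of the same number on every array, so both kinds were used as spike-ins; what DCP probes detect is not given in the sources used here.

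No probe could be named. A search of the gene tables for the probe prefix found 0 entries. The planned test of 21 lists of macrophage and treatment programmes and 11 lists of markers of other cell types was therefore not made, and neither was the count of changed genes. The rule for named genes was applied to probes: those of smallest p with a mean in the higher group above the median of all probes, no overlap between the groups and a change of at least 2-fold. It was held to 2 probes per direction, since the identifiers carry no gene name.

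The main test, fixed before the data were examined, was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the deposited log2 values of all 90752 mouse probes, with 1 term for chemotherapy, no block and no filter. Adjusted p-values are Benjamini-Hochberg over the probes tested, with a threshold of 0.05. With 3 samples against 3, an exact permutation test of a single value cannot go below 0.10, so none was used.

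Whether the replicate numbers pair the arrays was checked before the fits were compared. The deviations of same-numbered arrays from their group means correlated across probes at 0.54, 0.37 and 0.23 for numbers 1, 2 and 3. Every array correlated best with its own number in the other group, and the highest value between different numbers was 0.18. All 3 correlations exceeded 0.1, the limit used for treating the arrays as pairs, so the fit with the number as a block is given beside the main fit. Deviations from a mean of 3 arrays sum to 0, so a shift shared by number 1 alone also makes numbers 2 and 3 correlate. The values between numbers 2 and 3, 0.12 and 0.18, passed the limit too, so it cannot show these as separate pairs. On the brighter probes number 3 correlated at 0.50 with its own number and at 0.42 and 0.35 with number 2. The pairing comes from these data and the shared numbers, and no label states it.

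The alternatives were a shift of each array to 1 median, quantile normalization, leaving out the third of probes with the lowest mean over all arrays, an intensity trend with a robust prior, array weights, the replicate block, other thresholds, and leaving out each array. The paired fit on brighter probes, its settings, the random block, leaving out a replicate number in both groups and the shift to a common spike-in level were added after the data were seen. The bound for a probe near the floor used, on each array, the higher of its own value and the background line.

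The tests were tried on simulated arrays with 200 probes changed by known amounts. Each probe kept its real level, and its spread was the value that limma shrinks toward a common one. Such values vary less between probes than the real spread does. In the unpaired fit on 90752 probes, 6.06% of the probes changed by 1 on the log2 scale were recovered, 62.7% of those changed by 2 and 88.1% of those changed by 4, with 7 false calls. In the paired fit on 60501 brighter probes, 85.1% of the probes changed by 1 and 100% of those changed by 2 or 4 were recovered, with 22 false calls. These 22 were 10.4% of all calls of that simulation, and the 7 of the unpaired fit were 6.25% of its calls. Both shares lie above the 5% that the threshold aims at. The simulation assumes independent normal errors and applied no floor. In it, dim probes could fall below the lowest real values, so the recovery of large changes may be overstated. The simulation was run a single time per fit, with 200 changed probes, far below the 5000 calls of the real paired fit. Its rates therefore need not carry over to the real arrays.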

Results

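The series measured RNA from tumour-associated macrophages, the macrophages that live inside a tumour, taken from breast tumours of PyMT mice that had or had not received chemotherapy. PyMT mice carry the polyomavirus middle T antigen as a transgene and develop mammary tumours. The cells were isolated magnetically with a kit for mouse monocytes, and the RNA was labelled with Cy3 and hybridised to a 1-colour mouse array that covers mRNA and long noncoding RNA. There were 3 samples with and 3 samples without chemotherapy. The drug, its dose and its timing were not given in the sources used here. No source said whether the 3 samples of a group came from separate animals, so the tests measure only the spread between these samples.

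The table held 90808 probes on each of 6 arrays, of which 90752 were mouse probes and 56 were control probes. The mouse probes were named only by a running number, and neither the table nor the gene tables used here paired a number with a gene. The results therefore concern probes, and which of them belong to mRNA or to long noncoding RNA is not known here. On the log2 scale the values ran from 1.86 to 18.7, with a median between 6.46 and 6.47 on every array. Between 82.3% and 86.9% of the mouse probes on an array lay above a background line, set for each array as the higher of the negative control and the dark corner spots. The line lay between 2.07 and 2.47. On replicates 1, 2 and 3 it was 2.47, 2.37 and 2.08 without chemotherapy and 2.19, 2.08 and 2.07 with chemotherapy. The array without chemotherapy, replicate 3, differed at the floor: 11996 of its probes, 13.2%, held the same value of 1.96, while no value occurred on more than 2 probes of any other array. The number of arrays limits the precision of every value that follows.

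The 6 profiles were alike, with Pearson correlations across probes between 0.963 and 0.990; probes are not independent replicates. The array pair with the highest correlation was replicate 3 with and replicate 3 without chemotherapy. In a principal component analysis of the 60501 probes left after the dimmest 33.3% were set aside, named the brighter probes from here on, the first component held 58.9% of the variance and set both replicate 1 arrays apart from the other 4. The second component held 25.3% and put all 3 samples without chemotherapy below 0 (-61.5 to -35.1) and all 3 with chemotherapy above 0 (28.0 to 79.6). Such a split of 3 against 3 arises by chance for 10% of components if the 6 arrays are exchangeable.

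**Figure D1:**
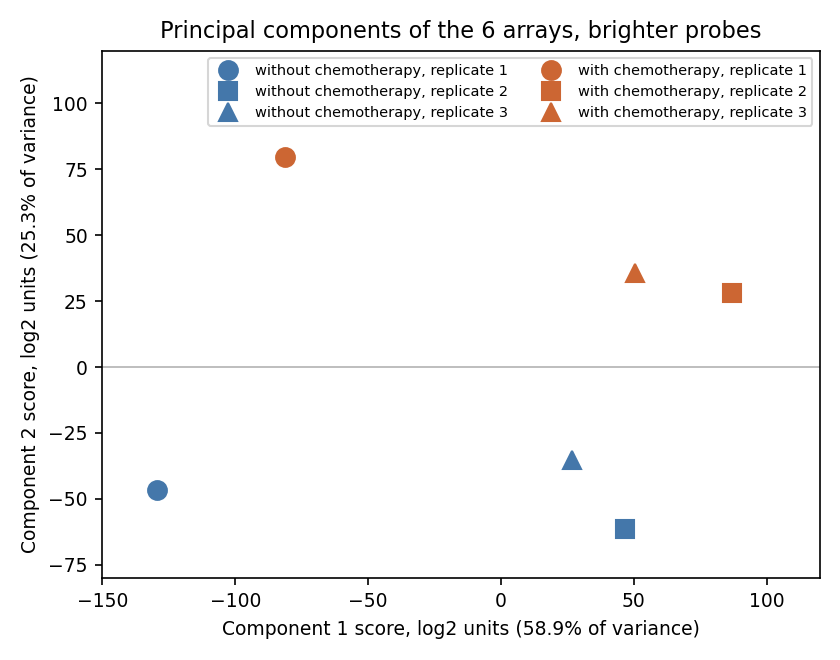
Scores of the 6 arrays on the first 2 principal components of the brighter probes, in log2 units; colour marks the group and symbol the replicate number. Replicate 1 of both groups lies at the left (-130 and -81.2 on component 1), and the groups are separated by the horizontal line at 0 on component 2.

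The spike-in controls also set replicate 1 apart. Transcripts of adenovirus E1A are added to each sample in fixed amounts, and 6 probes for them lay away from floor and saturation. A further 12 DCP control probes were counted with them, because DCP probes read close to the E1A probes of the same number; what they detect is not given in the sources used here. The mean of these 18 probes was 11.4 on replicate 1 without and 11.5 on replicate 1 with chemotherapy. It lay between 11.93 and 12.03 on the other 4 arrays. The gap of 0.42 on the log2 scale was larger than the range of 0.10 among those 4 arrays, and it was 0.46 with the 6 E1A probes alone. Within a replicate number the sample with chemotherapy read higher by 0.10, 0.052 and 0.029 for replicates 1, 2 and 3.

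**Figure D2:**
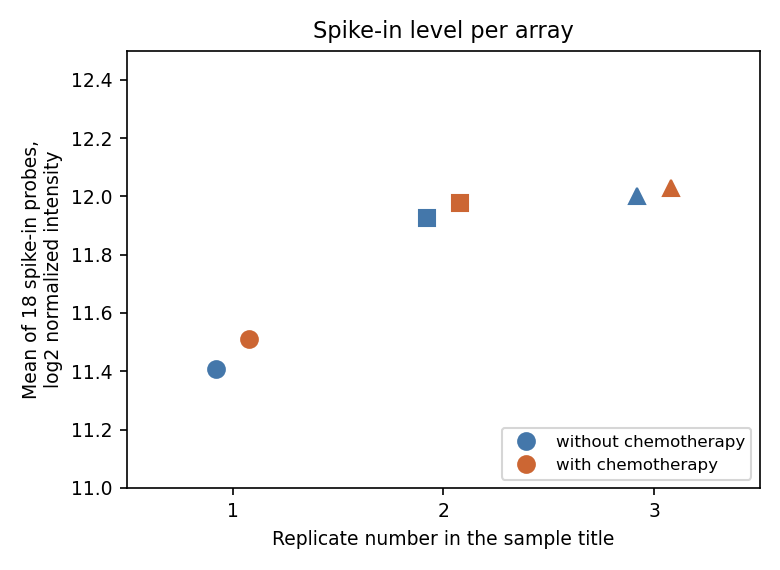
Mean log2 normalized intensity of 18 spike-in probes on each array against the replicate number in the sample title; the vertical axis does not start at 0. Both replicate 1 arrays (11.4 and 11.5) lie below the other 4 (11.93 to 12.03), whichever the group.

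The comparison of macrophages with against without chemotherapy asked which transcripts differ after treatment. Many probes moved the same way in all 3 same-numbered pairs of arrays. Among the brighter probes, 467 were at least 2-fold higher with chemotherapy in every pair and 374 were at least 2-fold lower, 841 in all. At 4-fold or more there were 93 higher and 31 lower. The differences of the 3 pairs correlated across the brighter probes at 0.62, 0.63 and 0.55. Over all mouse probes the correlations were 0.28, 0.30 and 0.22.

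In the unpaired test over all 90752 mouse probes, limma with Benjamini-Hochberg adjustment, 0 probes passed an adjusted p of 0.05. The smallest adjusted p in limma was 0.072. At an unadjusted p under 0.05 there were 6992 probes, 3472 higher and 3520 lower, against 4538 for independent and exchangeable arrays. Of the 6992, 1079 were at least 2-fold higher and 796 at least 2-fold lower. The replicate structure makes 4538 too simple a reference. Among the 10 ways to split the 6 arrays 3 against 3, 3 gave at least 6992 such probes, the real one included. With the replicate number as a block, limma again called 0 probes (smallest adjusted p 0.13), and 16977 probes lay under an unadjusted p of 0.05. Setting the dimmest 33.3% of probes aside gave 18 calls in the unpaired fit, 16 higher and 2 lower. Setting them aside and keeping the block, a combination chosen after the data were seen, gave 5000 calls, 8.26% of the brighter probes.

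In this paired fit on brighter probes, 1869 probes rose with chemotherapy and 3131 fell. Among calls of at least 2-fold, 747 rose and 758 fell, and among calls of at least 4-fold, 181 rose and 62 fell. Among calls of less than 1.5-fold, 328 rose and 757 fell. The median change of the probes that rose was 0.87 on the log2 scale, and that of the probes that fell was -0.74. With arrays shifted to a common spike-in level, which moves the median of the brighter probes by -0.06, 738 rose and 934 fell at 2-fold or more and 175 rose and 74 fell at 4-fold or more. The balance at 2-fold or more went either way with the setting. It stayed near even with array weights (730 rose and 750 fell). It did so too with the median shift (747 and 761) and quantile normalization (761 and 754), which moved the already aligned values little. More probes rose than fell under others: 938 rose and 816 fell with an intensity trend and a robust prior, 830 and 748 with a random block, 760 and 604 on the 45376 brightest probes, and 680 and 618 without the replicate 1 arrays. With a pair left out, and so 2 pairs in the fit, 0 probes were called without the replicate 2 arrays, 1 without the replicate 3 arrays and 2465 without the replicate 1 arrays, of which 2145 were among the 5000. All 5000 kept their direction in each of these 3 fits, which their selection on the same arrays favours.

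The calls were spread over the range of signal. The lower-level brighter probes, with a mean from 4.73 to 8.30, held 749 that rose and 1409 that fell, or 7.13% of 30250 probes. The 30251 probes with a mean above that held 1120 that rose and 1722 that fell, or 9.39%. At 2-fold or more the lower-level probes had 279 risen and 381 fallen, and the higher-level probes had 468 risen and 377 fallen. The median spread of a probe within a group was 0.25 at the higher level and fell to 0.10 once the replicate number was taken out. At the lower level these values were 0.27 and 0.15.

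A total of 4 probes were chosen by smallest p, 2 in each direction, under criteria fixed for genes before the data were examined; their use on probes and the limit of 2 per direction were set after the table was seen. The probe MOUSELNCRNA_32015 read 2.31 ± 0.44 (SD, n = 3) without chemotherapy, where it lay at or below the background line on 2 of 3 arrays, and 9.24 ± 0.52 (SD, n = 3) with chemotherapy. Between the group means, with the background line in place of lower values, it was at least 103-fold higher with chemotherapy. This bound is for the means and not for each pair. The log2 differences within replicates 1, 2 and 3 were 7.61, 7.36 and 5.83, without the line applied. The probe MOUSELNCRNA_87655, which was bright in both groups, read 10.6 ± 0.20 without and 13.1 ± 0.15 with chemotherapy (SD, n = 3), a log2 difference of 2.51 with a standard error of 0.15, or 5.71-fold. The probe MOUSELNCRNA_12906 read 8.25 ± 0.32 without and 5.40 ± 0.050 with chemotherapy (SD, n = 3), a log2 difference of -2.85 with a standard error of 0.18. The probe MOUSELNCRNA_67171 read 8.89 ± 0.10 without and 7.02 ± 0.18 with chemotherapy (SD, n = 3), a log2 difference of -1.86 with a standard error of 0.13. None of the 4 passed in the unpaired fit over all probes, with adjusted p in limma of 0.072, 0.089, 0.089 and 0.096 in the order given. In the unpaired fit on brighter probes all 4 passed, with adjusted p in limma between 0.032 and 0.043. In the paired fit on brighter probes the adjusted p in limma lay between 0.011 and 0.012.

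**Figure D3:**
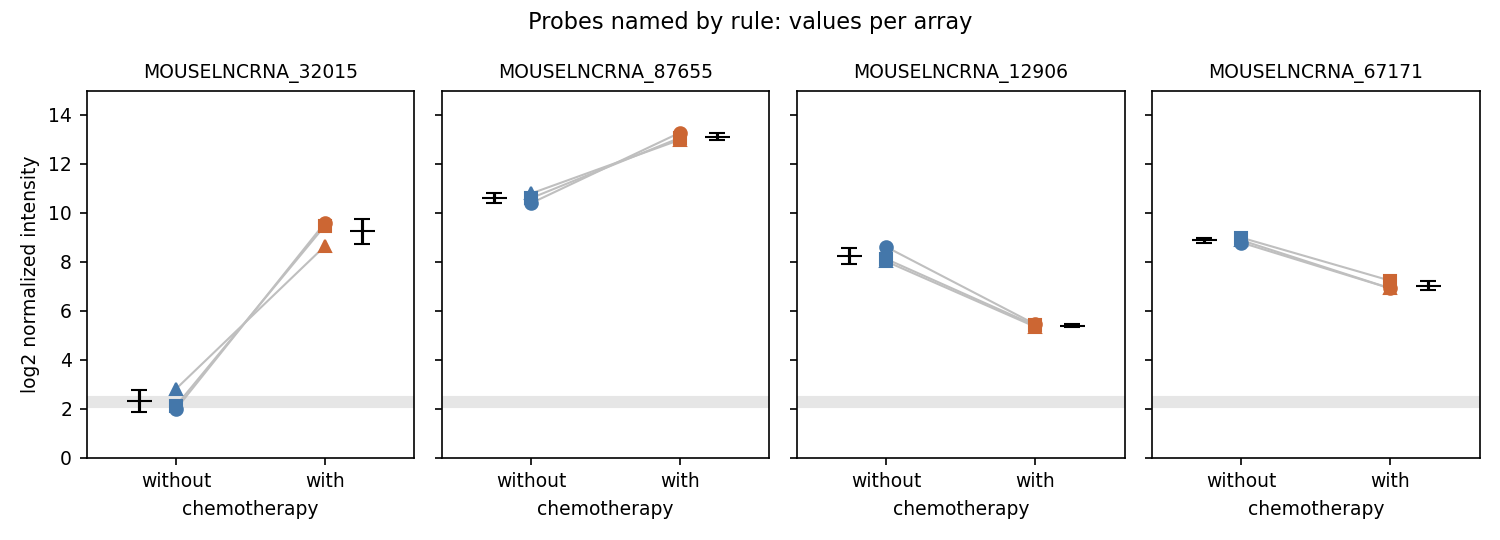
Log2 normalized intensity of the 4 probes on each array without (blue) and with (orange) chemotherapy; grey lines join arrays of the same replicate number (circle 1, square 2, triangle 3), black marks give the mean ± SD of 3 samples, and the grey band is the range of the background line. In every panel the groups do not overlap, which the rule for choosing the probes required, and MOUSELNCRNA_32015 starts at the background band.

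Without regard to any model, 5630 mouse probes were higher on all 3 arrays with chemotherapy than on all 3 without, and 6557 were lower. Together these were 13.4% of the probes, against 10% for exchangeable arrays, which the replicate structure makes too simple a reference. The share of non-overlapping probes was 11.2% in the dimmest sixth of probes and 16.1% in the brightest. Within pairs, 43.4% of all mouse probes moved one way in all 3 pairs, against 25% if each pair moved up or down at random. The patterns in which pair 3, 2 or 1 went against the others held 21.2%, 19.7% and 15.7%. Probes of an array shift together and there are only 3 pairs, so the 25% is too simple a reference as well. In the dimmest sixth the lower probes outnumbered the higher ones by 1379 to 308, with a median change of 0.15 on the log2 scale, and only 45 and 7 of them reached 2-fold. With replicate 1 without chemotherapy left out, 2428 were lower and 1758 higher, a ratio of 1.38 in place of 4.48. In the brightest sixth 1210 were higher and 1224 lower, of which 260 and 133 reached 2-fold.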

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

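Of the tests in this part, those of the spike-in levels by replicate number and of the splits for the unpaired and the paired fit were chosen after the result was seen; the spike-in shift was added after the data were seen, and for it and the splits with array weights only what they would show was written down before their results were computed.

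The control probe ETG05_36762 was higher on all 3 arrays with chemotherapy than on all 3 without, by 0.13 on the log2 scale. It drew attention as a signal in probes that no comparison used. Chance gives about 2.8 such probes among the 56 controls in each direction, and 1 was seen higher and 1 lower.

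Same-numbered arrays deviated together, most of all number 1. A difference in labelling or RNA input shared by both replicate 1 arrays may account for part of this: their spike-ins lay 0.42 below the lowest of the other 4 arrays, and 0.46 below with the 6 graded E1A probes alone. For numbers 2 and 3 the mean spike-in difference was 0.062, against 0.052 and 0.029 between the groups within a number, which does not decide the question, although their profiles still differed alike in both groups (r = 0.33 across the brighter probes). A shared day, litter or animal behind a number stays open as an untested biological explanation.

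The paired fit on brighter probes called 5000 probes where the planned fit called 0. When the arrays were shifted to a common spike-in level, 96.1% of the calls stayed past the threshold and all 5000 probes kept their direction. This speaks only to a scaling offset between the arrays of a pair as small as that in the spike-ins. The spike-ins of a pair differed by 0.10, 0.052 and 0.029, against a median change of 0.78 among the calls, so most calls could hardly be lost. They were also read after the authors' normalization, and a larger offset was not tested. The 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 5000 calls, a number reached by 1 split with the real one counted, and the highest of the others gave 0. Of the 9 others, 6 part a single pair, and the 3 that part every pair turn 1 pair, so a shared effect of chemotherapy would enter their residual spread and their counts say little. In the unpaired fit all 10 splits gave 0 calls, and 3 of the 10 gave at least the real 6992 probes at an unadjusted p under 0.05, the highest of the others being 13325 for a split that sets replicate 2 of both groups and replicate 3 with chemotherapy against the rest and so largely follows the replicate number. A change in the makeup of the isolated cells stays open, because no probe can be tied to a marker gene here.

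Array weights gave 2228 calls in the unpaired fit, but 3 of the 10 splits reached that number and the highest of the others, which parts all 3 pairs, gave 14600. The weights were 4.39 and 4.82 for the replicate 3 arrays against 0.29 and 0.35 for the replicate 1 arrays.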

How the results depend on the processing

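The planned count of 0 changed probes stayed at 0 under the intensity trend with a robust prior, the replicate block and the 2-fold minimum beside the adjusted p. It also stayed at 0 under the median shift and quantile normalization, which moved the already aligned values little and so test little. It became 18 without the dimmest 33.3% of probes (fewer probes, and a tighter variance prior), 2228 with array weights, and 1875 with an unadjusted p under 0.05 and a 2-fold change, which drops the adjustment. Of the alternatives added after the data were seen, a random replicate block gave 793 and the replicate block without the dimmest probes gave 5000. Leaving out an array, as planned, or a pair, as added after the data were seen, gave 0 to 2 calls. The 2 came without replicate 3 with chemotherapy. The 6992 probes at an unadjusted p under 0.05 became 20347 with array weights, 16977 with the replicate block, 15814 with a random block and 16423 with block and filter, and 4122 (without replicate 3 in both groups) to 9605 (without replicate 1 in both groups) when arrays were left out. The 5000 calls of the paired fit on brighter probes became 7976 with a trend and robust prior, 18 with no replicate block, 0 with no filter, 1505 with a 2-fold minimum, and 0 to 2465 when a pair was left out. They lay between 4900 and 6979 under the other settings, among them a random block, which kept 3662 of the same probes and direction. The share of risen probes was 37.4% and lay between 30.3% (spike-in shift) and 42.7% (random block) in the other settings with all 3 pairs, a block, a filter and no fold minimum; with the 2-fold minimum 747 rose and 758 fell. Each of the 4 named probes passed the threshold in 4 of the 17 alternatives to the main fit. These were the filter on dim probes and the array weights, both unpaired, and the random block and the block with the filter. Adjusted p in limma ran from 0.0063 to 1 over the alternatives. The mean correlation of the pair differences, 0.60, was 0.27 over all probes. With mismatched numbers the means were 0.084 and 0.077, from single values of opposite sign (0.0014, -0.29 and 0.54; -0.36, 0.37 and 0.22), of which the highest was close to the lowest matched value of 0.55. Except where stated, the cause was not tested. As to signal over background, the paired fit called 0 probes over all probes and 5000 without the dimmest 33.3%. Leaving these out changed both the number of tests and the variance prior. Fewer tests alone could not give the calls. The smallest adjusted p in limma over all probes was 0.13. At unchanged p-values, going from 90752 to 60501 tests cannot bring it under 0.05. The calls therefore needed the re-estimated prior as well, and the share of each was not measured. The settings for genes and gene lists were not run, because the probes could not be named.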

Other observations

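In this part, the size test of the dim probes and the test of tied values were chosen after the result was seen. The latter takes the place of a test set out before, on the probes not tied on the array concerned, which was set aside because it picked probes by their value on an array of the group without chemotherapy.

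In the dimmest sixth of probes, those lower with chemotherapy outnumbered the higher ones 4.48 to 1. Differences at the floor of the authors' scale may account for it. The median size of the change, 0.15 on the log2 scale, cannot decide this. These probes were chosen by means between 1.88 and 2.57, which leaves little room for larger changes. The tied values on the array without chemotherapy, replicate 3, are argued against as the whole cause: with that array left out, 3110 probes of the dimmest sixth were lower and 677 higher, a ratio of 4.59. The excess did depend on replicate 1 without chemotherapy, since without that array 2428 were lower and 1758 higher, a ratio of 1.38, while leaving out any 1 of the other 4 arrays gave ratios from 2.78 to 4.86. The dark corner spots were highest on that array, at 2.47, and averaged 2.27 without and 2.08 with chemotherapy. On replicate 3 they went the other way, 1.97 without and 2.07 with, and the negative control differed by only -0.03. Whether the background accounts for the excess was not tested. In the test set aside, 457 were lower and 82 higher among the 4275 probes not tied, and 922 and 226 among the 10851 tied. Quantile normalization left 1188 lower and 365 higher. No biological explanation was tested.

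The running numbers of the probes, 1 to 90752, carried no visible order. The change with chemotherapy of a probe and of its next number correlated at -0.0019 across probes, and their levels at -0.0011.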
